A study of Homo sapiens with 8 samples.

How the data were processed

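Nascent transcription was measured by global run-on sequencing (GRO-seq), in which engaged RNA polymerases are allowed to extend their transcripts in isolated nuclei and the labelled RNA is purified and sequenced. The 8 libraries came from 2 human cell lines, MCF7 (breast adenocarcinoma) and HCT116 (colon carcinoma). Each line was treated for 72 h with vehicle (DMSO) or with Akti-1/2, an inhibitor of the kinases AKT1 and AKT2, at 2 µM in MCF7 and 20 µM in HCT116. Each of the 4 groups held 2 libraries. Per the labels' protocols, nascent RNAs of about 100 nt were ligated to small RNA adapters, reverse transcribed, amplified, size-selected above 90 nt and sequenced on an Illumina HiSeq. No molecular identifiers are described, so amplified copies of 1 molecule cannot be recognised.

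The deposited values were RPKM (reads scaled to gene length and to the library's total), which the authors computed over gene bodies without the first 500 bp downstream of the transcription start site, per the file headers and the name of the table. The submitters' processing notes name cutadapt 1.2.1, Bowtie 0.12.9, bedtools 2.17.0 and the genome build hg19. The order of these steps, the handling of multiply aligned reads and of strand, and the total used in the RPKM are not given in the sources used here. Reads of genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are therefore uncertain, and so are those of overlapping or antisense genes. The table gives a symbol, a chromosome and a strand for each gene. Start and end positions were not used here, since no annotation of that build was at hand.

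The table held 24934 rows. Of these, 1825 had no finite value in every library and were left out: 215 had an infinite value and 1610 a value that is not a number, as genes no longer than the excluded stretch give. Where a symbol had more than 1 finite row (488 symbols), the row with the highest mean RPKM was used. The columns of values are named by cell line, AKT1 state and replicate number, not by treatment. Each was matched to a labelled library by its cell line, its cell state in the labels and its replicate number. Columns named AKT1WT were so taken as DMSO and those named AKT1Low as Akti. A mismatch between values and line label could therefore lie in the column names or in the libraries. The 6274 genes with a mean RPKM of at least 0.25 over the 8 libraries were tested.

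The RPKM values kept the steps of single reads, and the library totals were read from these steps. All 16263 finite rows above 0 came out as whole reads in every library (100.0%, relative tolerance 1e-06). The totals so obtained, the smallest set of whole numbers that the values allow, ranged from 5407632 reads (HCT116 DMSO replicate 1) to 125270173 reads (HCT116 DMSO replicate 2). The same steps gave each gene's counted length, the smallest whole number that turned its values into whole reads in every library. It can be a divisor of the true length, and the reads are then too low by the same factor. All gene lengths below are these counted lengths. The search for totals was tested on simulated tables and returned 6 of 6 totals. With the totals known, 99.05% of simulated rows gave their exact reads. GAPDH, which nearly every cell transcribes, was listed at 0 in 6 of the 8 libraries, so an exact 0 is reported only as listed at 0, and values are given per library.

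Values were taken as log2(RPKM + 0.1), a scale that understates the change of weakly transcribed genes. A rule fixed before the data were examined asked for a common median if replicates differed by more than 0.2 in their median. They differed by 0.906 in the MCF7 DMSO group, 0.393 in the HCT116 Akti group, 0.21 in the HCT116 DMSO group and 0.053 in the MCF7 Akti group, so each library was shifted to the same median. On the values as deposited, the median of all tested genes lay 0.47 higher in Akti than in DMSO libraries of MCF7 and 0.45 higher in HCT116. In MCF7 this went with DMSO replicate 1 alone. The MCF7 medians were -1.067 and -0.161 in DMSO and -0.12 and -0.173 in Akti, replicates 1 and 2 in turn. All fold changes below are relative to the shift of the medians between Akti and DMSO.

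All 4 groups entered 1 limma model (limma 3.58.1, R 4.3.3, variance trend, 4 residual degrees of freedom, two-sided, Benjamini-Hochberg adjusted p under 0.05). The comparisons were Akti against DMSO in each line, the difference of these 2 responses, and HCT116 DMSO against MCF7 DMSO. The dose differed between the lines, so line and dose cannot be told apart in the difference. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. An exact permutation test of 2 against 2 libraries cannot go below 0.33. Gene lists fixed beforehand were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move one way without comparing them with other genes. Of 36 lists, 32 had at least 5 tested members. The replication-dependent histone list had 4, the fibroblast and endothelial lists 1 each and the blood cell list 0.

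On simulated values with the spread of the real libraries, for the comparison of MCF7 Akti with DMSO over 6274 genes, the model recovered 0 of 50 genes changed 2-fold, 2 of 50 changed 4-fold, 8 of 50 changed 8-fold and 18 of 50 changed 16-fold. It also called 2 unchanged genes. At 0.2 times that spread it recovered 41 of 50 genes changed 2-fold and called 17 unchanged genes. The spread used was the one shared by all 4 groups. These counts therefore also rest on libraries whose line-specific genes went against or mixed with their label.

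Named genes followed a rule set beforehand. It took the 8 largest rises and falls past the adjusted p with a mean RPKM of at least 1 and no overlap between groups, and up to 4 members of each list past it or, with none, the 2 with the highest mean RPKM. It also took AKT1, AKT2 and AKT3, members of the line marker lists, and 5 genes in each direction for the other comparisons. Genes outside the rule are said to have been chosen after their values were seen. Alternatives were values as deposited, quantile normalization, pseudocounts of 0.01 and 1, no filter, a mean RPKM of at least 1, no variance trend, a robust variance model, voom weights from the whole reads, all rows as separate features, the libraries of 1 line alone, each library left out, and the replicate number as a block. After the data were seen, a fit without the 3 libraries whose line-specific genes went against or mixed with their label was added, as well as a fit with the length trend of each library removed (loess, span 0.5) and the differences of the replicate 2 libraries alone. Intervals of list medians are 95% bootstrap intervals over genes (10000 draws) and leave out the spread between libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.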

Results

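Gene-body transcription was profiled by GRO-seq in MCF7 cells, an estrogen receptor-positive breast adenocarcinoma line, and HCT116 cells, a colon carcinoma line, after 72 h of vehicle or of Akti-1/2. The inhibitor was used at 2 µM in MCF7 and 20 µM in HCT116, and each of the 4 groups had 2 libraries. The RPKM values rested on 39707065 and 51100785 reads in the libraries labelled MCF7 DMSO, 43291342 and 53460460 reads in MCF7 Akti, 5407632 and 125270173 reads in HCT116 DMSO, and 37344303 and 52167275 reads in HCT116 Akti, replicates 1 and 2 in turn. The median tested gene was covered by 124 reads in the shallowest of these and by 3387.5 in the deepest. Where 2 values are given for a group below, they are those of replicates 1 and 2.

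Genes that mark the lines were examined first, because they check the labels. The breast genes ESR1 (the estrogen receptor, chromosome 6), GATA3 (a luminal transcription factor, chromosome 10) and PGR (the progesterone receptor, chromosome 11) were transcribed in all 4 libraries labelled MCF7. ESR1 stood at 2.09 and 4.88 RPKM in MCF7 DMSO and at 0.878 and 5.38 RPKM in MCF7 Akti. In the replicate 2 libraries labelled HCT116 it stood at 0.0094 RPKM (DMSO) and 0.0024 RPKM (Akti), but in the replicate 1 libraries of that label at 3.01 RPKM (DMSO) and 1.39 RPKM (Akti). GATA3 was at 1.44 and 0.0044 RPKM in the libraries labelled HCT116 DMSO, and PGR at 3.29 and 0.0017 RPKM. Conversely EREG (epiregulin, chromosome 4) and AKAP12 (a kinase anchoring protein, chromosome 6), from the colon marker list, were at 9.11 and 5.70 RPKM in the library labelled HCT116 DMSO replicate 2. In replicate 1 of that group they were at 0.016 and 0.0031 RPKM, while the library labelled MCF7 Akti replicate 1 held them at 9.68 and 2.32 RPKM. Not every marker divided the libraries this way. FOXA1, from the breast list, was at 2.815 RPKM in HCT116 DMSO replicate 2, against 1.721 and 1.541 RPKM in MCF7 DMSO. DKK1, from the colon list, was at 0.003 RPKM in HCT116 DMSO replicate 2, against 2.276 and 0.469 RPKM in MCF7 DMSO. Of the 36 colon markers only 6 passed the filter.

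The division shown by ESR1, EREG and AKAP12 also held over line-specific genes, which were defined after the data were seen, from the replicate 2 libraries alone. These had at least 1 RPKM in both libraries of 1 line and at most 0.05 RPKM in both of the other. The 64 MCF7 genes had a median level of 71.3% of their level in the defining libraries in the library labelled HCT116 DMSO replicate 1 (bootstrap interval 60.1 to 78.6%), and the 40 HCT116 genes 0.17% (0.03 to 0.33%). In HCT116 Akti replicate 1 both sets were present, at 35.6% and 30.9%. In MCF7 Akti replicate 1 they were at 18.5% and 63.5%, and in MCF7 DMSO replicate 1 at 47.2% and 0.0%. Among all pairs of libraries, the highest correlation across genes, which are not independent replicates, was between MCF7 DMSO replicate 1 and the library labelled HCT116 DMSO replicate 1 (Pearson's r 0.95, Spearman's rho 0.94). The libraries labelled HCT116 DMSO replicates 1 and 2 gave r = 0.48. The whole reads of that first pair still differed by more than sampling noise (chi-square of 28.7 per degree of freedom over 5661 genes). This covers counting error alone, since copies made by amplification cannot be recognised, and does not show that they are separate samples. Both were kept as labelled. Groups follow the labels throughout, and every direction below that rests on HCT116 DMSO, HCT116 Akti or MCF7 Akti includes a library whose line-specific genes went against or mixed with its label.

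**Figure D1:**
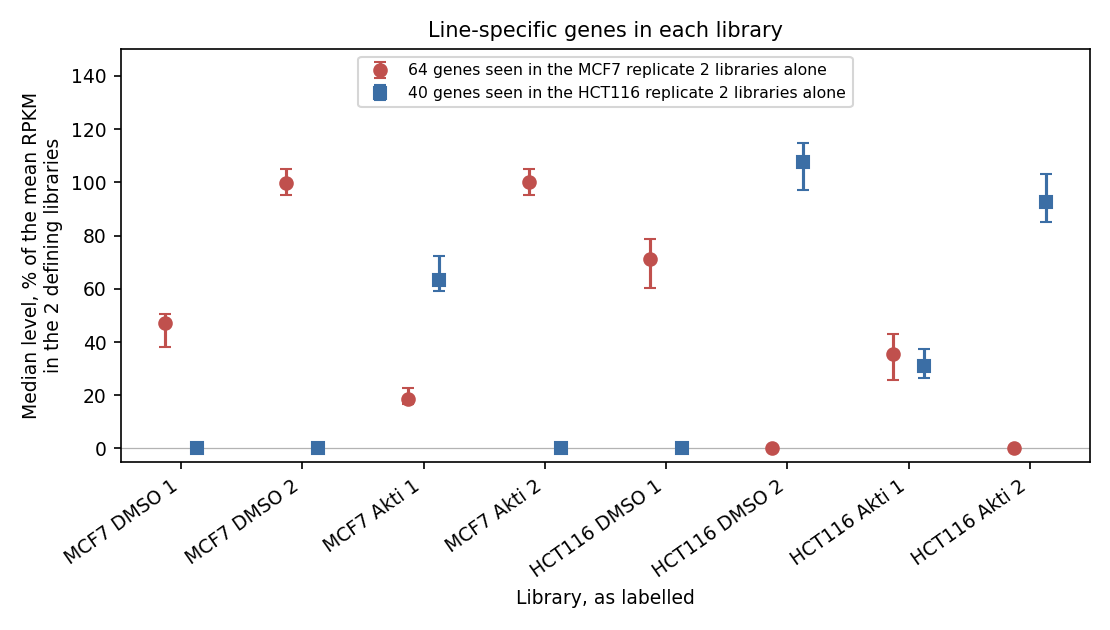
Median level of 64 genes seen in the MCF7 replicate 2 libraries alone (circles) and of 40 genes seen in the HCT116 replicate 2 libraries alone (squares) in each library, in percent of their mean RPKM in the 2 defining libraries, with 95% bootstrap intervals over genes. The library labelled HCT116 DMSO replicate 1 lies at 71.3% for the MCF7 genes and 0.17% for the HCT116 genes, and HCT116 Akti replicate 1 and MCF7 Akti replicate 1 hold both sets.

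**Figure D2:**
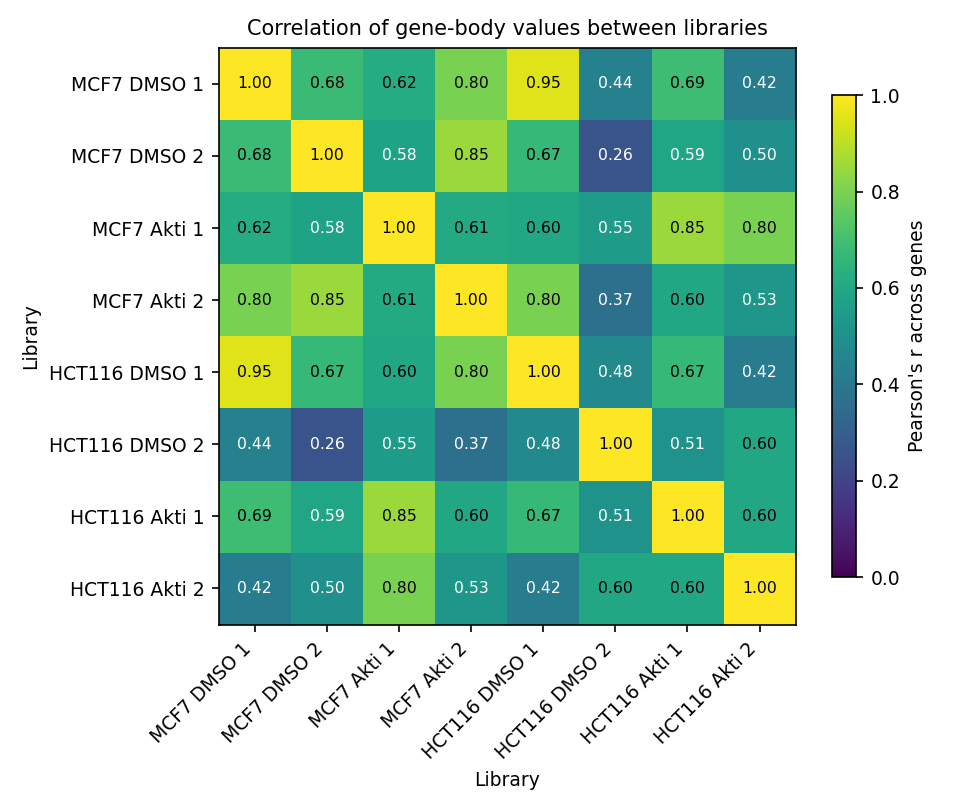
Pearson's r between libraries across the 6274 tested genes, on log2(RPKM + 0.1) with each library at the same median. The value between MCF7 DMSO replicate 1 and the library labelled HCT116 DMSO replicate 1 is 0.95, and that between the 2 libraries labelled HCT116 DMSO is 0.48.

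The first comparison asked how AKT inhibition alters transcription in MCF7. Genes of the cell cycle, of the immediate early response and of the ribosome were called higher as lists in the MCF7 Akti libraries, but no single gene passed the test. With an estimated inter-gene correlation none of these lists was called (camera adjusted p = 0.67 to 0.74). Of 31 mitotic genes, 30 had a higher fitted value with the inhibitor, with a median log2 fold change of 1.01. The 29 DNA replication genes had a median of 0.67, the 25 immediate early and serum response genes 1.26 and the 55 ribosomal protein genes 0.33. BUB3, a mitotic checkpoint protein (chromosome 10), stood at 0.348 and 2.22 RPKM in DMSO and at 2.66 and 4.65 RPKM in Akti. CENPE, a kinetochore motor (chromosome 4), stood at 2.48 and 0.201 RPKM in DMSO and at 3.31 and 2.18 RPKM in Akti. The replication clamp PCNA (chromosome 20) was at 0.638 and 5.60 RPKM against 7.13 and 7.06 RPKM, and the ribonucleotide reductase subunit RRM2 (chromosome 2) at 0.154 and 0.848 RPKM against 5.47 and 1.37 RPKM. IER3, an immediate early gene on chromosome 6, was at 0.0296 and 0.0919 RPKM in DMSO and at 20.1 and 0.132 RPKM in Akti, so that its difference lay in the replicate 1 library, which held genes of both lines.

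By camera with the preset correlation, these 4 lists of the 32 were called higher: mitosis (adjusted p = 1.7e-15), immediate early and serum response (8.3e-08), DNA replication (6.5e-05) and ribosomal proteins (0.011). With an estimated correlation the adjusted p was 0.67 for the mitosis, DNA replication and immediate early lists and 0.74 for the ribosomal proteins. No member of these lists rose or fell, over all genes tested or adjusted over the list alone. Both Akti libraries lay above both DMSO libraries for 11 mitotic genes, 13 replication genes, 6 immediate early genes and 8 ribosomal protein genes, where 11.3% of all tested genes did so and chance gives 16.7%. Without MCF7 DMSO replicate 2 the mitosis median fell to 0.23 (adjusted p = 0.48 with the preset correlation) and the DNA replication median to 0.07 (adjusted p = 0.71). Without MCF7 Akti replicate 1 the immediate early median was -0.02 (adjusted p = 0.20). The ribosomal protein median was -0.22 without MCF7 DMSO replicate 1, 0.04 without MCF7 Akti replicate 1 and 0.04 without the 3 libraries at odds with their label. On values as deposited that list was not called (median 0.8, camera adjusted p = 0.17). Nor was it with voom weights (0.36, camera adjusted p = 0.065) or with the length trend removed (0.02, camera adjusted p = 0.66).

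Genes of the AKT pathway itself did not pass any test in MCF7. AKT1 (chromosome 14) stood at 0.0195 and 1.48 RPKM in DMSO and at 0.208 and 0.117 RPKM in Akti, and its log2 fold change was -1.22 ± 1.08 (SE, n = 2 libraries per group, limma adjusted p = 0.999). AKT2 and AKT3 lay under the filter, at no more than 0.15 and 0.01 RPKM in the MCF7 libraries. Of 20 AKT pathway components, 5 had a higher and 15 a lower fitted value (median -0.33, camera adjusted p = 0.10). Among them RPS6KB1, the kinase of ribosomal protein S6, was at 17.6 and 18.2 RPKM in DMSO and at 6.88 and 29.0 RPKM in Akti, and IRS1, the insulin receptor substrate, at 3.98 and 9.53 RPKM against 6.45 and 11.2 RPKM. The 18 FOXO targets, genes bound by transcription factors that AKT restrains, had a median of -0.02. TXNIP, a thioredoxin inhibitor, was at 13.9 and 27.2 RPKM in DMSO and at 9.57 and 11.1 RPKM in Akti, and KLF6 at 3.81 and 0.969 RPKM against 4.83 and 2.66 RPKM. The receptor tyrosine kinases had a median of 0.89 over 9 genes (camera adjusted p = 0.70), with IGF1R at 2.51 and 7.04 RPKM against 1.22 and 7.52 RPKM. The estrogen receptor targets had a median of -0.57 over 30 genes and the luminal breast markers -0.71 over 24 genes. These lists share many members, ESR1, PGR, GREB1 and XBP1 among them, and are not independent. Neither was called (camera adjusted p = 0.059 and 0.079), and both medians moved with the replicate 1 library, in which these markers were low.

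In the gene-wise test of MCF7 Akti against DMSO, limma called 0 of 6274 genes higher and 0 lower. At an unadjusted p under 0.05 there were 26 higher and 5 lower, where chance gives 313.7, and voom weights also called 0. The smallest adjusted p was 0.999, and the median standard error of a log2 fold change was 0.70. The spread behind that standard error was shared by all 4 groups, including the libraries at odds with their line label. The gene with the smallest unadjusted p, chosen after its value was seen, was TMSB10 (thymosin beta 10, chromosome 2). It was listed at 0 and at 0.0729 RPKM in DMSO and stood at 1.89 and 2.33 RPKM in Akti.

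**Figure D3:**
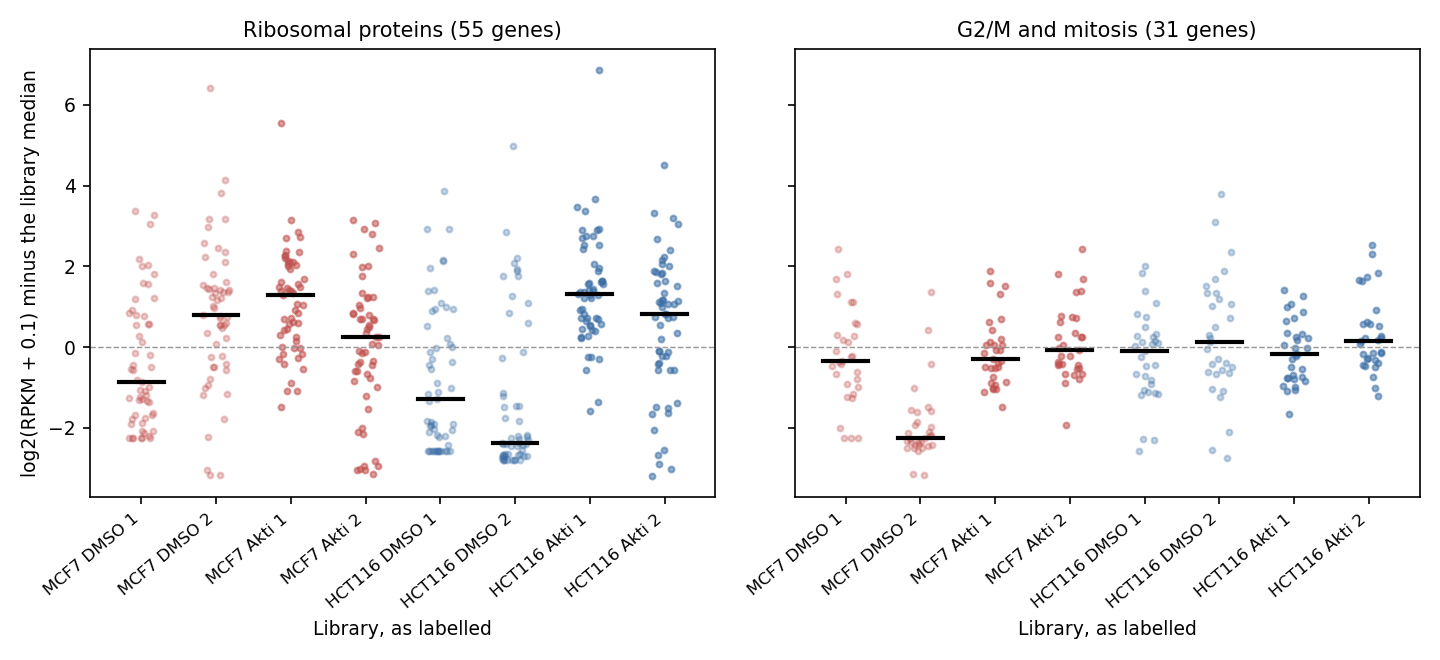
Values of 55 ribosomal protein genes (left) and 31 mitotic genes (right) in each library, as log2(RPKM + 0.1) minus the median of all tested genes of that library. Each point is a gene and each bar the list's median. The mitotic genes lie at -2.26 in MCF7 DMSO replicate 2 and between -0.33 and 0.16 in the other libraries, and the ribosomal protein genes at -1.29 and -2.37 in the libraries labelled HCT116 DMSO and at 1.31 and 0.81 in HCT116 Akti.

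The same question was asked of HCT116, at the higher dose. Ribosomal protein genes were higher in the HCT116 Akti libraries, with a median log2 fold change of 2.19 over 55 genes, of which 51 had a higher and 4 a lower fitted value. The list was called with the preset correlation (camera adjusted p = 9e-17) but not with an estimated one (adjusted p = 0.58) or by fry (adjusted p = 0.41). Both Akti libraries lay above both DMSO libraries for 37 of the 55, where 17.9% of all tested genes did so and chance gives 16.7%. RPL17 (chromosome 18) stood at 1.08 and 2.82 RPKM in DMSO and at 89.0 and 22.7 RPKM in Akti. RPL9 (chromosome 4) did not share this, at 8.55 and 21.6 RPKM in DMSO and 8.40 and 9.85 RPKM in Akti. Over all genes tested no member rose, and adjusted over the list alone 5 rose and 0 fell. RPL13A on chromosome 19 had the smallest unadjusted p of all genes and was chosen after its values were seen. It was at 0.308 and 0.103 RPKM in DMSO and at 4.28 and 3.62 RPKM in Akti. RPL13AP5, listed on the same chromosome and strand, had nearly proportional values (0.35 and 0.12 against 4.76 and 4.08 RPKM), so both may rest on the same reads.

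Further lists called higher in HCT116 Akti were immediate early and serum response genes (median 1.33 over 25 genes), ATF4 and amino acid response genes (0.72 over 24), heat shock genes (0.71 over 22), DNA replication genes (0.51 over 29) and translation factors (0.39 over 35). With an estimated correlation none of them was called (adjusted p = 0.58 for each), and the heat shock list lost its call when any 1 of the 4 HCT116 libraries was left out (adjusted p = 0.061 to 0.16). KLF10, an immediate early transcription factor on chromosome 8, nevertheless stood at 22.7 and 28.3 RPKM in DMSO and at 14.5 and 8.55 RPKM in Akti, while IER3 was listed at 0 and at 0.0281 RPKM in DMSO and stood at 21.8 and 1.12 RPKM in Akti. The amino acid transporter SLC38A2 (chromosome 12) was at 48.9 and 255.5 RPKM against 63.6 and 63.7 RPKM, and the asparagine synthetase gene ASNS (chromosome 7) at 2.73 and 4.37 RPKM against 4.70 and 10.8 RPKM. The chaperones HSPD1 (chromosome 2) and HSP90AA1 (chromosome 14) were at 2.10 and 0.796 RPKM and at 2.39 and 0.370 RPKM in DMSO, and at 5.49 and 21.7 RPKM and at 4.08 and 11.1 RPKM in Akti. PCNA was at 0.894 and 0.618 RPKM against 3.24 and 22.1 RPKM, and RRM2 at 0.111 and 0.161 RPKM against 1.17 and 12.4 RPKM. The translation factors PABPC1 (6.80 and 28.4 against 17.3 and 25.4 RPKM) and EIF4A1 (18.2 and 5.90 against 20.1 and 9.99 RPKM) overlapped between the groups. The 31 mitotic genes had a median of 0.20 and were not called (camera adjusted p = 0.56).

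With the preset correlation these further calls had adjusted p = 0.0024 for immediate early, 0.021 for ATF4, 0.023 for DNA replication, 0.025 for translation factors and 0.029 for heat shock genes. Without the library labelled HCT116 DMSO replicate 1, ribosomal proteins were the 1 list still called (median 2.66), and the same held without the 3 libraries at odds with their label (median 2.22). The lists that lost their call without that DMSO library kept a positive median, at 0.57 for DNA replication, 0.53 for translation factors, 1.14 for heat shock, 0.88 for immediate early and 0.51 for ATF4 genes. Without HCT116 Akti replicate 2, DNA replication (median 0.44, adjusted p = 0.15) and translation factors (0.35, adjusted p = 0.19) lost their call as well, and so did ATF4 genes without HCT116 Akti replicate 1 (0.77, adjusted p = 0.062). The size of some medians hung on single libraries: that of ATF4 genes was 1.69 without HCT116 DMSO replicate 2 and 0.25 without the 3 libraries, and that of translation factors was 0.76 without HCT116 DMSO replicate 2 and 0.83 without HCT116 Akti replicate 1. Short genes as a whole had lower values in the HCT116 DMSO libraries, above all in replicate 2, than in Akti. With genes split into 5 groups by counted length, as read from the RPKM steps, the shortest group (up to 14 kb) had a median log2 fold change of 0.99 and the longest -0.45. Relative to each library's median over all tested genes, the shortest group lay at -0.62 and -1.95 in HCT116 DMSO. In HCT116 Akti it lay at 0.28 and -0.03, and in MCF7 DMSO at -0.58 and 0.09. After each library's length trend was removed the ribosomal protein median was 1.07 (adjusted p = 7.1e-07). DNA replication also stayed called (median 0.48, adjusted p = 0.027), while translation factors (0.13, adjusted p = 0.25), ATF4 (0.55, adjusted p = 0.085), immediate early (0.79, adjusted p = 0.27) and heat shock genes (0.42, adjusted p = 0.25) lost their call. With voom weights all 5 further lists lost it (adjusted p = 0.15 to 0.41), at medians of 0.60 for DNA replication, 0.43 for translation factors, 1.03 for heat shock, 0.66 for ATF4 and 0.86 for immediate early genes.

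AKT1 was listed at 0 and at 0.0099 RPKM in HCT116 DMSO and stood at 0.379 and 0.195 RPKM in Akti (log2 fold change 1.39 ± 1.08 SE, n = 2 libraries per group, limma adjusted p = 0.70). AKT2 and AKT3 lay under the filter, at no more than 0.425 and 0.037 RPKM. Of the 20 AKT pathway components, 15 had a lower fitted value (median -0.49, camera adjusted p = 0.31). IRS1 was at 10.6 and 37.0 RPKM in DMSO and at 8.71 and 5.76 RPKM in Akti, and RPS6KB1 at 22.3 and 1.05 RPKM against 10.1 and 2.70 RPKM. The FOXO targets had a median of 0.09 (camera adjusted p = 0.53). TXNIP showed the division of the libraries, at 16.8 and 0.0087 RPKM in DMSO and at 14.4 RPKM and listed at 0 in Akti.

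Gene by gene, limma called 0 of 6274 genes in HCT116 Akti against DMSO. At an unadjusted p under 0.05 there were 331 higher and 111 lower, where chance gives 313.7 in all, and voom weights also called 0. The smallest adjusted p was 0.659. Among genes lower in Akti, SPINT1 (a protease inhibitor, chromosome 15) had the smallest unadjusted p and was chosen after its values were seen. It was at 1.03 and 3.35 RPKM in DMSO and at 0.262 and 0.404 RPKM in Akti.

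The responses of the lines were then set against each other. Ribosomal protein genes had a larger log2 fold change in HCT116 than in MCF7, by a median of 1.74 (50 of 55 genes), as did heat shock genes, by 0.91 (15 of 22). Mitotic genes had a smaller one, by -1.05 (26 of 31 genes). By camera the adjusted p of these differences was 8.2e-13, 0.039 and 9.6e-05, and with an estimated correlation adjusted p = 0.93 for each. With the length trend removed the ribosomal protein difference was 0.95, and the median of that list in MCF7 was 0.02 (adjusted p = 0.66). Without MCF7 DMSO replicate 2 the mitotic difference was -0.07 (adjusted p = 0.98), and the heat shock difference kept its call in 10 of 23 alternatives. For single genes limma called 0 of 6274 differences, with 67 at an unadjusted p under 0.05, and 0 with voom weights. No gene passed in both lines, in the same or opposite directions. Across genes, which are not independent replicates, the fitted responses of the lines correlated with r = 0.39 and rho = 0.34. This rested on the replicate 1 libraries. Akti minus DMSO of the replicate 1 libraries correlated between the lines with r = 0.77, and that of the replicate 2 libraries with r = -0.20, as the map of list medians also shows. At an unadjusted p under 0.05, 10 genes moved the same way in both lines and 1 the opposite way. No chance value is set beside these counts, because the replicate 1 libraries resembled each other across the lines and the comparisons are therefore not independent. One of the 10, named after its values were seen, was CCNA2 (cyclin A2, chromosome 4), at 0.303 and 0.098 RPKM in MCF7 DMSO, 1.31 and 2.76 RPKM in MCF7 Akti, 0.265 and 0.336 RPKM in HCT116 DMSO, and 1.42 and 3.46 RPKM in HCT116 Akti.

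**Figure D4:**
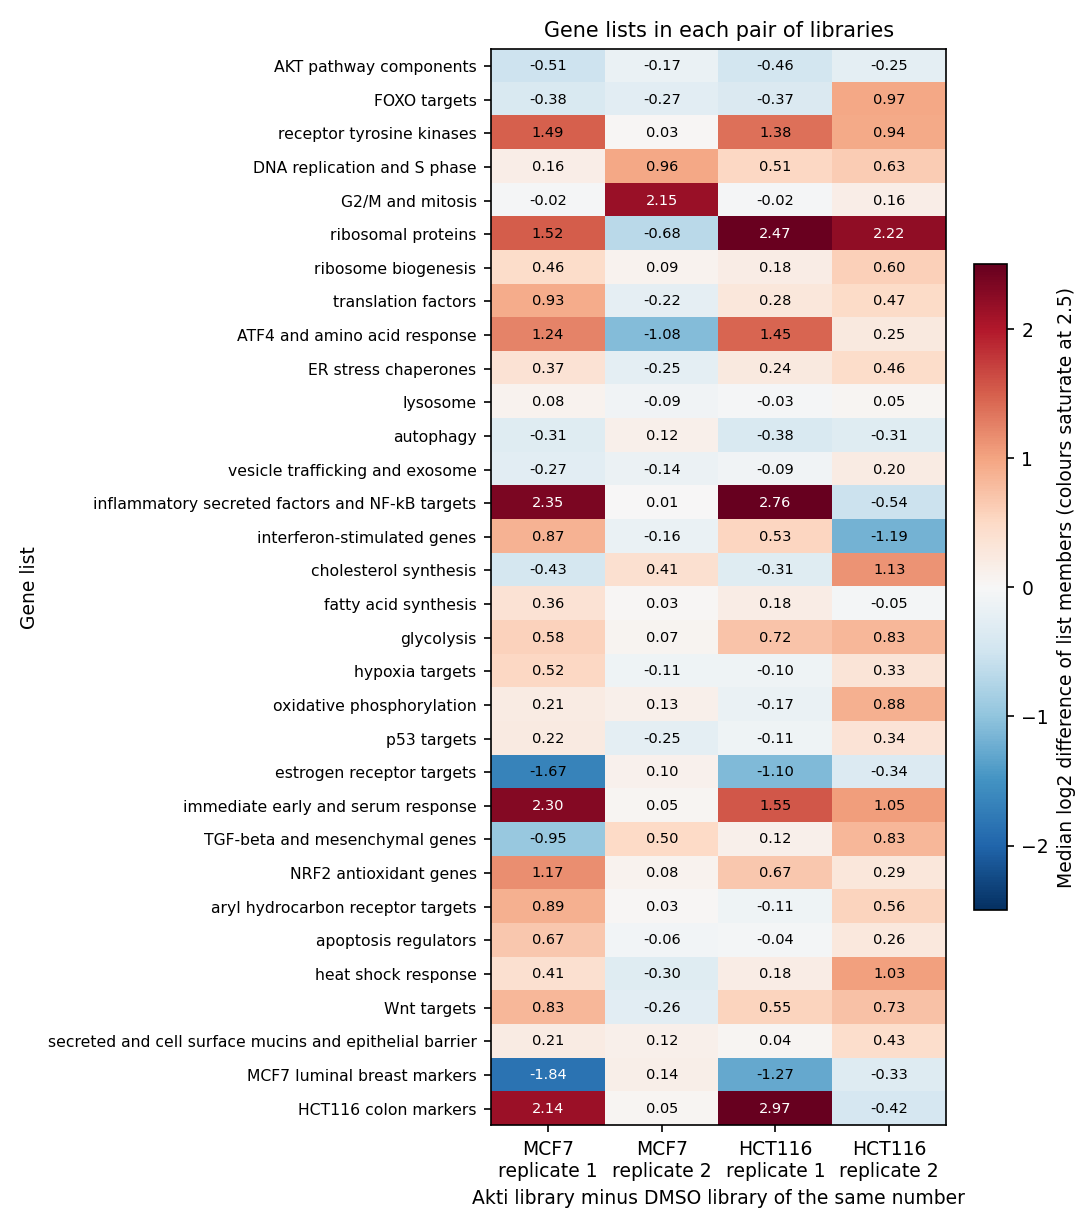
Median log2 difference between the Akti and the DMSO library of the same replicate number for the members of each of 32 gene lists (log2(RPKM + 0.1), libraries at the same median). The replicate 1 columns of both lines are high for immediate early (2.30 and 1.55) and low for luminal breast genes (-1.84 and -1.27), the mitotic genes are high in the MCF7 replicate 2 column alone (2.15), and the ribosomal protein genes are high in 3 columns and at -0.68 in MCF7 replicate 2.

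Last, the vehicle-treated libraries labelled HCT116 DMSO were compared with those labelled MCF7 DMSO, although replicate 1 of the former resembled MCF7. Estrogen receptor targets (median -1.5, 28 of 30 genes lower) and luminal breast markers (median -1.61, 22 of 24 lower) were lower in HCT116 DMSO, as were ribosomal proteins (median -1.44, 49 of 55) and heat shock genes (median -1.16, 16 of 22). Mitotic genes were higher (median 0.88, 27 of 31). The breast lists share many members, ESR1, PGR, GREB1 and XBP1 among them, and so are not independent results. The camera adjusted p was 0.00069 for both breast lists, 2.9e-07 for ribosomal proteins, 0.013 for heat shock and 1.3e-05 for mitosis, and with an estimated correlation adjusted p = 0.87 for all 5. ELOVL2, a fatty acid elongase on chromosome 6 and an estrogen receptor target, stood at 16.3 and 37.0 RPKM in MCF7 DMSO and at 29.0 and 0.0188 RPKM in the libraries labelled HCT116 DMSO. TRPS1, a transcription factor of luminal cells on chromosome 8, was at 8.22 and 14.7 RPKM against 14.4 and 0.0076 RPKM. Without HCT116 DMSO replicate 2 the estrogen receptor target median was 0.11 and that of the luminal markers 0.01 (adjusted p = 0.99 for both), and without HCT116 DMSO replicate 1 they were -2.94 and -3.06. Without MCF7 DMSO replicate 2 the mitosis median was 0.09 (adjusted p = 0.65), the heat shock median -0.64 (adjusted p = 0.11) and the ribosomal protein median -0.72 (adjusted p = 0.0055). The heat shock list also lost its call without HCT116 DMSO replicate 1 (median -1.41, adjusted p = 0.2), with voom weights (-1.41, adjusted p = 0.15), at a mean RPKM of at least 1 (-0.61, adjusted p = 0.14) and with the length trend removed (-0.67, adjusted p = 0.073). With that trend removed the ribosomal protein list stayed called, at a median of -0.66. The colon marker list, with 6 tested members, had a median of 1.18 and was not called (camera adjusted p = 0.38). EREG was listed at 0 in both MCF7 DMSO libraries. No gene passed limma's test (312 at an unadjusted p under 0.05, where chance gives 313.7, and 0 with voom weights), and the smallest adjusted p was 0.646.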

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

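Of the tests in this part, those of snoRNA host genes and of the gene length trend were set out before their results were seen, and the others after. The gene set for the test of a response to the inhibitor was replaced after its first version, which used the library it tested, had been run. The bounds of the tests of a mixture of lines and of HCT116 DMSO replicate 2 alone were reworded after their results were seen, and under the first wording the ribosomal protein results counted against both.

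Of the 4 replicate 1 libraries, 3 carried genes of a line other than their label. The remaining one, MCF7 DMSO replicate 1, held the HCT116 genes at 0.0% (0.0 to 0.17%). The MCF7 genes stood at 71.27% of their level in the library labelled HCT116 DMSO replicate 1 and the HCT116 genes at 0.17%, which is consistent with material mostly from MCF7 under an HCT116 label. In HCT116 Akti replicate 1 and MCF7 Akti replicate 1 both sets were present, the lowest of the 4 medians being 18.54%, which is consistent with material of both lines in each. A swap between libraries of 1 line each needs an MCF7-labelled library without MCF7 genes, and the lowest median of these genes in such a library was 18.54%. An exchange of labels between the 2 Akti libraries holding both lines stays open, since the one labelled MCF7 had more of the HCT116 genes (63.48%) and the one labelled HCT116 slightly more of the MCF7 genes (35.59% against 30.92%). A response to the inhibitor is argued against by MCF7 Akti replicate 2. There, 122 HCT116 genes chosen on the DMSO replicate 2 libraries alone stood at 0.41% (0.11 to 1.0%), against 31.89% (21.75 to 38.02%) in MCF7 Akti replicate 1. In HCT116 Akti replicate 2 they stood at 35.92%. The vehicle-treated library among those out of place argues against such a response too. Whether cells, RNA or indexed reads were mixed was not tested.

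Ribosomal protein genes were called for a difference between the responses of the lines, by a median log2 difference of 1.74, and lay 2.19 higher in HCT116 Akti than in DMSO. With an estimated correlation neither was called (adjusted p = 0.93 and 0.58), nor by fry (0.98 and 0.41). Reads from small nucleolar RNAs in the introns of host genes are argued against as the whole cause, because the 30 members outside a list of hosts written from general knowledge had a median of 1.82 (1.32 to 2.47), against 2.22 in the 25 hosts (permutation p = 0.25). Gene length is likewise argued against as the whole cause: the median was 1.07 (0.72 to 1.29) with the trend removed, and length-matched random lists had a median of 1.18, with the list's value at percentile 100 of 10000 such lists. Part of the difference may go with length. Low values in HCT116 DMSO replicate 2 alone cannot be told apart from a response: the median without that library was 1.98 (1.31 to 2.40), but the DMSO library then left is the one resembling MCF7. A mixture of lines cannot be told apart either. The replicate 2 pair gave 2.22, and so did the fit without the 3 libraries, which rests on the same 2 HCT116 libraries and kept the call, but that is 1 library per group. The medians of the MCF7 pairs, which include a library holding both lines, differed by 2.2, and the list lay at -0.85 and 0.79 in the MCF7 DMSO libraries, where the HCT116 genes stood at 0.0% and 0.01%. A response to AKT inhibition stays open and untested.

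Mitotic genes were called for a difference between the responses, by a median of -1.05, but not with an estimated correlation (adjusted p = 0.93) or by fry (adjusted p = 0.98). The higher values in MCF7 Akti went with 1 library, MCF7 DMSO replicate 2, without which the median was 0.23. A mixture of lines in the replicate 1 libraries is argued against, because the replicate 1 pair, which holds the mixed library, gave -0.02, the replicate 2 pair 2.15 (1.79 to 2.37), and the fit without that mixed library, with both MCF7 DMSO libraries, 1.04. With the length trend removed the median was 0.98 (0.82 to 1.25). Whether MCF7 DMSO replicate 2 differed in growth state or in preparation was not tested.

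Heat shock genes were called for a difference between the responses of the lines, by a median of 0.91. The call was lost with an estimated correlation (adjusted p = 0.93) and kept with a positive median in 10 of 23 alternatives, while 1 of the others had a negative median. Across these alternatives the median ranged from -0.02 to 1.65. Genes no longer than the excluded 500 bp, whose values were infinite wherever they had reads, were outside all comparisons. Those with reads numbered 12 and 25 in the HCT116 DMSO libraries and 112 and 105 in HCT116 Akti. Most were small nucleolar RNA and microRNA genes (in HCT116 Akti replicate 2, 49 of the SNORD, 19 of the SNORA and 29 of the MIR kind). HCT116 DMSO replicate 1 was the shallowest library and resembled MCF7, and depth was not allowed for in these counts. In MCF7 those with reads numbered 19 and 67 in DMSO and 124 and 60 in Akti.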

How the results depend on the processing

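The fits without the 3 libraries at odds with their label, with 1 residual degree of freedom, and with the length trend removed were added after the data were seen; the other alternatives were planned. Counts of 0 genes held in all 4 comparisons under every alternative except 1: without a filter, 2910 of 16232 genes were called in HCT116 Akti against DMSO. Of these, 2754 lay under the filter, all lower with a median of -1.16, which is the shift of 1.16 that a common median over untranscribed genes imposes, so the setting's own construction accounts for them, and 156 lay past the filter. No gene passed in both lines under any alternative run.

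The number of lists called by camera moved more. In MCF7 it was 4, and 7 with quantile normalization, 12 without a filter, 9 with only the MCF7 libraries, 8 with the replicate block, 0 with an estimated correlation and 0 by fry, and 3 to 15 when single libraries were left out. In HCT116 it was 6, and 14 without a filter, 2 at a mean RPKM of at least 1, 1 with voom weights, 1 without the 3 libraries at odds with their label, 2 with the length trend removed, 0 with an estimated correlation and 0 by fry, and 1 to 9 when single libraries were left out. For the difference it was 3, and 6 without a filter, 1 at a mean RPKM of at least 1, 0 with an estimated correlation, 0 by fry and 1 to 6 when single libraries were left out. For the DMSO comparison it was 5, and 9 without a filter, 0 with an estimated correlation, 0 by fry and 3 to 6 when single libraries were left out. The cause of these changes in the number of lists called was not tested.

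Medians changed direction in these cases. In MCF7, ribosomal proteins were at -0.22 without MCF7 DMSO replicate 1 (1.01 without replicate 2), and immediate early genes at -0.02 without MCF7 Akti replicate 1 (1.91 without replicate 2) and at -0.02 without the 3 libraries. In HCT116 without a filter, on the scale shifted by 1.16, DNA replication was at -0.20, translation factors at -0.32 and ATF4 genes at -0.09. Immediate early genes were at -0.04 and heat shock genes at -0.22 on that scale. Without a filter the heat shock difference between lines was -0.02, into which the MCF7 shift, not given here, also enters. In the DMSO comparison without HCT116 DMSO replicate 2, estrogen receptor targets were at 0.11 and luminal markers at 0.01, and without replicate 1 of that group at -2.94 and -3.06. Across all list calls, 321 alternatives kept the call and direction, 92 lost the call and 11 had a median of the other sign. The last count rests on the sign of the median, not on camera. Without a filter, camera still called DNA replication (adjusted p = 3.8e-06), translation factors (3.8e-06) and ATF4 genes (3e-06) in HCT116. Others of the 11, such as estrogen receptor targets without HCT116 DMSO replicate 2, had no call. For named genes, 2604 fits kept their side, 246 changed sign without a call and 4 gained a call, all 4 without a filter. Leaving out a library assumes that the lone one of its group varies like the others.

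Deviations of same-numbered libraries correlated from -0.44 to 0.36 between groups, and the labels give no common day. The replicate 1 libraries nevertheless resembled each other across lines (r = 0.95 for DMSO and 0.85 for Akti), so shared material or handling is not excluded, and the cause was not tested. With the replicate block, 0 genes were called in each comparison. Depth limits HCT116 DMSO replicate 1 most, with 5407632 reads and 410 of 6274 tested genes at 0.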

Other observations

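All observations in this part were chosen after the data were seen, and each comes from 1 library per group, so no test applies. They were picked from 32 lists in 4 pairs of libraries, among which some percentiles this far out arise by chance. The random lists used below were not matched on gene length. In the HCT116 replicate 2 pair the differences went with length (Spearman's rho -0.36). In the replicate 2 libraries, where ESR1 was transcribed mainly under the MCF7 label and EREG mainly under the HCT116 label, cholesterol synthesis genes lay higher with the inhibitor in both lines. The median log2 difference over 14 genes was 0.41 in MCF7, at the 98.1th percentile of 10000 random lists matched on mean expression, and 1.13 in HCT116, at the 99.1th. In HCT116 this went with low values in DMSO replicate 2, where the list lay at -0.99 relative to the library median. It lay at 0.66 in DMSO replicate 1 and at 0.47 and 0.37 in Akti. HMGCR, the rate-limiting enzyme of the pathway (chromosome 5), stood at 2.98 RPKM in MCF7 DMSO and 4.13 RPKM in MCF7 Akti, and at 1.55 and 4.18 RPKM in HCT116. In the replicate 1 libraries the medians were -0.43 and -0.31, and the joint fit gave -0.01 in MCF7 and 0.24 in HCT116 with no call. TGF-beta and mesenchymal genes showed the same sign in both replicate 2 pairs (0.50 at the 99.3th percentile in MCF7 and 0.83 at the 94.3th in HCT116), but in the replicate 1 pairs the medians were -0.95, at the 0.6th percentile, in MCF7 and 0.12 in HCT116.

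ATF4 and amino acid response genes went opposite ways in the MCF7 pairs, with a median of 1.24 over 24 genes in replicate 1 and -1.08 in replicate 2, where 5 of the 24 were higher. ASNS stood at 5.60 RPKM in MCF7 DMSO replicate 2 and at 0.468 RPKM in MCF7 Akti replicate 2. FOXO targets, which AKT restrains, had a median of 0.97 in the HCT116 replicate 2 pair, at the 98.1th percentile, and of -0.27 in the MCF7 replicate 2 pair, at the 2.6th. In the replicate 1 pairs it was -0.37 in HCT116 and -0.38 in MCF7. Interferon-stimulated genes had a median of -1.19 over 10 genes in the HCT116 replicate 2 pair, at the 0.9th percentile, but of 0.53 in the replicate 1 pair, where 9 of the 10 were higher, and the joint fit did not call the list (adjusted p = 0.61). HLA-B, the member with the highest mean, stood in the replicate 2 pair at 399.1 RPKM in DMSO and 25.2 RPKM in Akti.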
